A study of Mus musculus with 21 samples.

How the data were processed

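RNA was measured by sequencing in hearts of C57BL/6J mice. Per the labels' protocols, RNA was prepared with a miRNeasy kit, mRNA was captured by its polyA tail, and libraries were made with the Ion Total RNA-Seq Kit v2 and barcode primers. The series lists 21 samples: 7 hearts without storage (baseline C), 7 stored for 6 h with vehicle (6h-I), 3 stored with BM MSC CM and 4 stored with Ad MSC CM. The labels call baseline C a control with no ischemia and 6h-I 6 h ischemia with vehicle. Storage in the text stands for this ischemia in the cold, and the 2 cannot be told apart in this design. STAR 2.4.2a and featureCounts from Subread 1.5.0 with the mouse build mm10 are named in the submitters' processing notes, which give them no order or settings. The gene annotation and the strand setting used for counting are not given in the sources used here.

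The authors deposited 2 tables of CPM, counts scaled to the total reads of each library. The header of the second names this unit; for the first, whose header names none, it was read from the values, which rise in steps of 1 read. The first, called the storage table here, holds 266 genes in 4 baseline C and 3 6h-I libraries. Its columns name the group but no replicate, so its libraries are called a, b, c and d, which are names only and pair nothing. The second, called the media table, holds 89 genes in 2 baseline C, 3 6h-I, 3 BM MSC CM and 4 Ad MSC CM libraries, each named by replicate and barcode. Baseline C 3' and 6h-I 2' of that set have no column there. Columns of the storage table do not say whether either is among its libraries, whose group sizes are those of the samples numbered without a prime. No library of the media table has the same values as a library of the storage table, and 27 genes are in both. Both tables hold only selected genes. The smallest ratio of group means between 6h-I and baseline C, taken in either direction, was 1.31 in the storage table and 1.52 in the media table, and the row order followed that ratio with a Spearman rho of 0.97 and -1.0, respectively, across genes. The genes therefore appear to have been picked on these same libraries, and a count of changed genes or a p-value within a table is not independent evidence of a change with storage.

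The depth of each library was read from its lowest values, which are whole multiples of what 1 read is worth. All values (100%) lay within 0.05 of a read of a whole number. A single read was worth 0.0579 to 0.0751 CPM in the storage table and 0.0641 to 0.1024 CPM in the media table. A floor of 3 reads was 0.174 to 0.225 CPM in the storage table and 0.192 to 0.307 CPM in the media table; it covers counting error only. The listed genes summed to 14577 to 17138.7 CPM per library in the storage table and to 2896.7 to 3725.7 CPM in the media table. The reads of the listed genes can thus be recovered, but a count model on them was not run.

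Each table was tested alone, because no table holds both sets of libraries. The test was limma 3.58.1 (R 4.3.3) on log2(CPM + 1), with a trend of the variance on the mean, over genes with a median CPM above 1. The filter kept 255 genes and removed 11 in the storage table, and kept 85 and removed 4 in the media table. All 4 groups of the media table shared 1 estimate of the spread. P-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. The design was fixed before the data were examined and named this test for normalized values, with a count test for counts. It had foreseen set tests of lists for a full table with values per library; as these tables hold selected genes only, Fisher's exact test, foreseen for selected genes, took their place. The 27 genes in both tables were also fitted together in limma with a term for the difference in the storage change between the 2 sets of libraries. Labels do not say that replicates came from separate animals beyond calling them samples, so p-values measure the spread between these samples.

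The steps were tested on simulated data with the libraries' own means and spread. In 20 draws the storage comparison recovered 89.7% of genes changed 2-fold and 58.2% of those changed 1.5-fold, and called 1.7% of unchanged genes. BM MSC CM against 6h-I recovered 79.5% and 42%, Ad MSC CM against 6h-I 79.8% and 46.2%, and BM MSC CM against Ad MSC CM 82% and 48.8%, with 1.7%, 1% and 1% of unchanged genes called. Each draw changed 60 of 255 genes by each fold in the storage table, and 20 of 85 in the media table. Recovery where few genes change, with a stricter adjusted threshold, was not simulated and may be lower. The draws also varied each gene independently and did not model the apparent picking of genes, so these rates need not hold for the real libraries.

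The same design fixed 35 gene lists for pathways and cell types, together with the rule for the genes named in the text. The rule takes, per comparison, the 10 largest rises and 10 largest falls past the threshold, up to 4 genes of each list with at least 3 members past it, and 18 genes that are always given where present. A list's direction was tested within a table by a two-sided Fisher's exact test of membership against rise or fall among the genes past the threshold, for lists with at least 3 such members, adjusted over 8 lists in the storage table and 4 in the media table. A library's position on the storage change was computed as the projection of its log2(CPM + 1) values on the difference between 6h-I and baseline C, so that the mean of baseline C is 0 and the mean of 6h-I is 1. Positions were compared between groups by exact two-sided permutation tests, adjusted over 3 comparisons. The share of genes that moved against the storage change in a preparation was set beside 10000 simulated unchanged groups, once without any storage effect and once with it kept, because the comparison of a preparation with 6h-I and that of 6h-I with baseline C share the 6h-I libraries.

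Gene positions and transcript lengths come from GENCODE release M21 on GRCm38, the assembly also named mm10. Of 328 genes in either table, 308 matched by symbol, 18 by an older symbol and 2 did not match. Of 69 genes named in any comparison or flagged that have a position, 17 overlap another protein-coding gene, among them Dbp with Sphk2, Cebpb with Tmem189 and Junb with Prdx2 on the opposite strand. Values of genes overlapped on the opposite strand are uncertain to the extent that counting ignored the strand. Per3 with Camta1, Manf with Rbm15b and 5930430L01Rik with Gm42791 overlap on the same strand, so their values may be uncertain either way. Hspa1a and Hspa1b are near-identical copies, and their reads may have been divided between them by the counting.

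Alternatives were other pseudocounts (0.1 and 5), no filter, stricter thresholds (adjusted p of 0.01, absolute log2 fold change over 1 and over 2), the genes with the higher mean, plain gene symbols only, the replicate number as a block, and leaving out each library in turn. Further alternatives were chosen after seeing the data: each library's position on clock genes as a term, neighbouring barcodes as a block (17 to 19, 21 with 22, 23 with 24 and 25 with 26, a choice among neighbours since 24 and 25 adjoin as well), the shares without the clock list, leaving out libraries for the shares and lists, and the comparisons of each preparation with baseline C. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.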

Results

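Mouse hearts were kept cold outside the body for 6 h, with vehicle (6h-I) or with BM MSC CM or Ad MSC CM, preparations of the mesenchymal stromal cell secretome, and were compared with hearts that were not stored (baseline C). The labels name 6h-I as 6 h ischemia with vehicle and baseline C as a control with no ischemia. Transcript levels were available as CPM for 2 sets of libraries. The storage table held 4 baseline C and 3 6h-I libraries, in which 255 genes lay above the filter on low values and 1 read was worth 0.0579 to 0.0751 CPM. The media table held 2 baseline C, 3 6h-I, 3 BM MSC CM and 4 Ad MSC CM libraries, with 85 genes above the filter and 0.0641 to 0.1024 CPM to a read. The authors had selected the genes of both tables, apparently on the same libraries, so that counts of changed genes describe these lists and not the transcriptome. Values are mean CPM ± SD, and fold changes are on the log2(CPM + 1) scale.

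The question of what 6 h of cold storage did to the heart was asked of the selected genes in the storage table. The largest fitted rise was that of Arntl, the transcription factor that drives the positive limb of the circadian clock (chromosome 7, 113207465 to 113314126, GRCm38). It went from 3.05 ± 1.84 CPM (n = 4) in baseline C to 16.1 ± 1.76 CPM (n = 3) in 6h-I, a log2 fold change of 2.18 (SE 0.27, limma adjusted p = 0.000104). Per2, a clock repressor (chromosome 1, 91415982 to 91459324), fell from 57.1 ± 13.4 to 17.8 ± 5.47 CPM, a log2 fold change of -1.65 (SE 0.24, adjusted p = 0.000222). The deepest fall was that of Zbtb16, a transcriptional repressor induced by glucocorticoids (chromosome 9, 48654297 to 48836222), from 126.6 ± 40.6 to 36.3 ± 12.4 CPM, or -1.78 on the log2 scale (SE 0.27, adjusted p = 0.000268). Nppb, which encodes the natriuretic peptide BNP (chromosome 4, 147985788 to 147987205), rose from 103.7 ± 52.6 to 270.1 ± 86.4 CPM, with a log2 fold change of 1.43 (SE 0.29, adjusted p = 0.00153).

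All 10 members of the circadian list that were tested passed the threshold, adjusted over the table and adjusted over the list alone. So did 246 of all 255 genes tested (96.5%), as the genes were selected, and only 10 of the 23 list genes were in the table. Arntl rose, while Per2, Per3, Cry1, Cry2, Dbp, Tef, Hlf, Ciart and Wee1 fell. Hlf, a PAR bZIP output gene, fell by 1.09 on the log2 scale (51.3 ± 4.97 to 23.6 ± 2.69 CPM) and the cell cycle kinase gene Wee1, a clock target, fell by 1.19. Dbp, a direct output of the clock, fell by 0.68 (152.6 ± 6.31 to 96.1 ± 19.8 CPM, SE 0.17, adjusted p = 0.00538). With 9 of 10 members lower against 101 lower and 135 higher among the other changed genes, the list passed Fisher's exact test (p = 0.00594, adjusted p = 0.0475). Leaving out 1 library at a time gave adjusted p-values from 0.0367 to 0.076 for this list; the call ended without baseline C a, b or c and without 6h-I a or b, and also without the filter on low values (adjusted p = 0.0537).

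Of the 46 genes in the immediate-early and stress list 7 were in the table, and all 7 were higher (Junb, Ier2, Gem, Errfi1, Jun, Rcan1 and Fosl2). This did not pass Fisher's exact test after adjustment (p = 0.0179, adjusted p = 0.0716) but did without 6h-I b (adjusted p = 0.0477) or 6h-I c (adjusted p = 0.0246). Junb, an AP-1 subunit, went from 22.95 ± 15.2 to 55.9 ± 12.1 CPM, a log2 fold change of 1.47 (SE 0.39, adjusted p = 0.00576). The 3 heat shock genes present were all higher, again short of the list test (adjusted p = 0.681). Hspa1a, an inducible HSP70 gene (chromosome 17, 34969190 to 34972156), stood at 42.0, 5.76 and 8.06 CPM in the 6h-I libraries against 1.08 to 5.93 CPM in baseline C, so that its log2 fold change of 1.85 (SE 0.50, adjusted p = 0.00624) had a wide interval and its groups overlapped. Its near-identical copy Hspa1b followed it, at 38.4, 3.47 and 5.15 CPM in the same libraries, and Dnajb1, an HSP40 co-chaperone, rose by a log2 fold change of 0.90.

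The unfolded protein response, lipid, matrix, interferon and glucocorticoid lists were each split in direction, and none of these 5 passed the list test. In the unfolded protein response list Manf, a secreted ER stress protein, was higher (log2 0.64) while Chac1 (-1.03) and Herpud1 (-0.61) were lower, with an adjusted p of 0.941. Of 3 subunit genes of oxidative phosphorylation, Ndufa13 (log2 0.43) and Ndufb9 (0.62) rose, and Uqcr11 had a log2 fold change of 0.43 that did not pass (adjusted p = 0.0672); with 2 members past the threshold this list was not tested. In lipid handling Acot1 (0.83) and Plin5 (0.50) rose and Ucp2 fell by 0.71 (list adjusted p = 1.0). Of the 5 genes of the extracellular matrix list in the table, the 4 above the filter were 2 higher and 2 lower. The collagen gene Col3a1 (0.76), also in the fibroblast marker list, and the membrane protease gene Mmp14 (0.77) rose. The protease inhibitor genes Timp3 and Timp4 fell by 0.86 and 0.63 (list adjusted p = 1.0). Adamts4, under the filter, had a log2 fold change of 0.89 and was higher in every 6h-I library. Outside the list, the matrix genes Spon2 (1.89) and Col5a3 (1.42) rose, so the even split holds for the tested list members only. Among interferon-stimulated genes Iigp1 and Gbp5 fell by 0.70 and 0.67 and Bst2 rose by 0.46 (list adjusted p = 0.941). Of the glucocorticoid and fasting targets, Cdkn1a (1.01) and Errfi1 (0.93) were higher and Zbtb16 and Foxo3 (-0.64) lower (list adjusted p = 1.0).

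Outside the lists, Spon2, an extracellular matrix protein gene, rose from 2.54 ± 2.36 to 10.6 ± 2.42 CPM (log2 1.89), and Slc41a3, a member of the magnesium transporter family 41, from 48.8 ± 10.6 to 145.9 ± 31.9 CPM (log2 1.56). Cldn5, the claudin of endothelial tight junctions and the single gene of the endothelial marker list present, rose from 36.0 ± 8.0 to 114.3 ± 58.1 CPM (log2 1.54), with 61.6, 104.7 and 176.6 CPM in the stored hearts. Col5a3 (1.42) and Apold1 (1.24) completed the 10 largest rises. Lonrf1 (-1.56), Rhobtb1 (-1.37), Mthfd1l (-1.27), Wipf3 (-1.24), Chd6 (-1.19) and Cys1 (-1.11) were among the 10 largest falls. Tnf, the inflammatory cytokine, lay under the filter at 0.42 ± 0.20 CPM in baseline C and 1.54 ± 0.80 CPM in 6h-I. Of the 18 genes to be given wherever present, 13 were in neither table, Il6, Ccl2, Cirbp and Myh6 among them, and 13 of the 35 lists had no gene in either table, including those for sarcomere genes, mitochondrially encoded transcripts and myeloid markers.

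**Figure D1:**
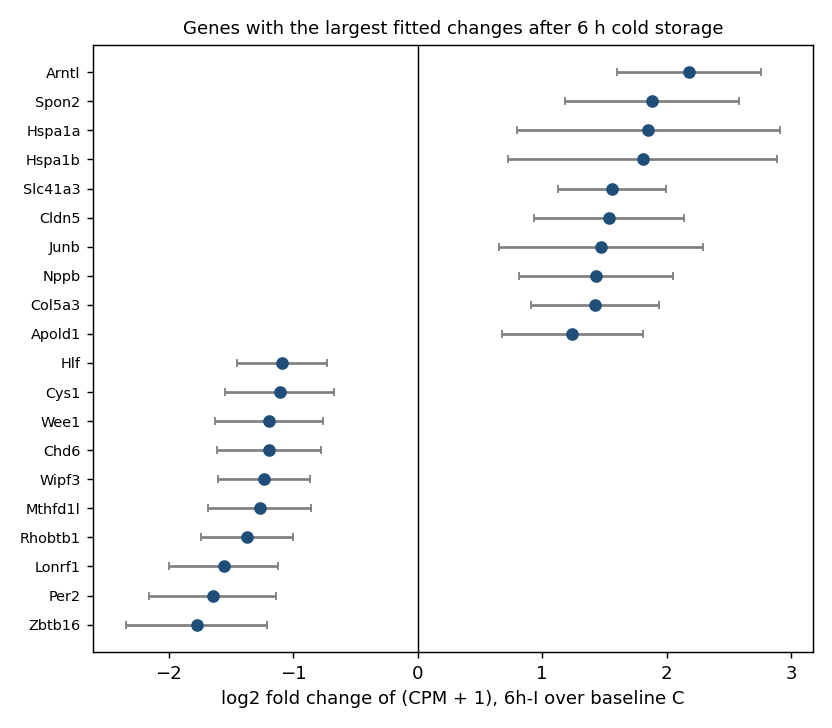
Fitted log2 fold change of (CPM + 1), 6h-I over baseline C, for the 10 largest rises and 10 largest falls of the storage table, on the horizontal axis; bars are 95% confidence intervals from limma (n = 4 and n = 3). Arntl lies highest at 2.18 and Zbtb16 lowest at -1.78, and the intervals of Hspa1a and Hspa1b are the widest.

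In all, 246 of 255 genes tested passed the threshold in the storage table, 136 higher and 110 lower in 6h-I (limma). Without 6h-I c the count was 183, with 90 higher and 93 lower, and of 40 named genes past the threshold 6 lost their call when some library was left out, namely Bst2, Col3a1, Herpud1, Manf, Plin5 and Timp4. Genes that rose had shorter transcripts than genes that fell, with medians of 2324 and 4681 nt for the longest annotated transcript (permutation p = 1e-05, the smallest that 100000 permutations can give).

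The second set of hearts, in the media table, gave the same comparison in other libraries. Arntl again rose, from 7.55 ± 4.19 CPM (n = 2) to 35.4 ± 9.14 CPM (n = 3), a log2 fold change of 2.16 (SE 0.48, adjusted p = 0.0037). Its partner Npas2 rose by 1.70 and Nfil3, a repressor that opposes Dbp, by 1.25, while 8 clock genes fell (Dbp, Ciart, Per3, Per2, Hlf, Tef, Bhlhe41 and Nr1d2). Dbp went from 94.1 ± 17.6 to 14.3 ± 7.98 CPM, a log2 fold change of -2.75 (SE 0.75, adjusted p = 0.00538), and Per3 from 77.0 ± 23.9 to 20.6 ± 6.02 CPM, or -1.86. The circadian list had 3 members higher and 8 lower, which did not pass Fisher's exact test after adjustment (p = 0.0234, adjusted p = 0.0937).

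The 5 hypertrophy and fetal program genes present were all higher (adjusted p = 0.16 for the list), among them the stress transcription factor gene Atf3 (2.99 ± 0.31 to 11.9 ± 5.02 CPM, log2 1.63), Thbs1 (1.29), Nppb (1.29) and Rcan1 (0.87). All 4 matrix genes were higher (list adjusted p = 0.195): the aggrecanase gene Adamts4 (1.48), Thbs1, the elastin gene Eln (1.01) and Ctgf (0.77). Of 5 immediate-early and stress genes, 4 rose, and Arc fell by 0.96 (list adjusted p = 0.644). Hspa1a (2.04), Hspa1b (1.53), Spon2 (2.30), Fam124b (1.62), Cdkn1a (1.53) and Col5a3 (1.42) were also among the largest rises, and Dixdc1 (-1.35), Gstt2 (-1.10), 5930430L01Rik (-1.10), Rasd2 (-1.02) and Sv2a (-0.98) among the largest falls. Alas2, of haem synthesis in red cells, lay under the filter, with 5.25 and 5.88 CPM in baseline C and 0.16, 1.40 and 0.44 CPM in 6h-I.

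All 85 genes tested passed the threshold in this comparison, 51 higher and 34 lower (limma). Without baseline C 2' the count was 56, and Cdkn1a, Ciart, Errfi1, Gstt2, Hspa1b, Per2, Rcan1 and Thbs1 lost their calls. Of the 27 genes in both tables, 26 had the same direction of storage change in the 2 sets of hearts. This covers only genes selected in both tables. Only 27 of the 89 genes in the media table were also in the storage table, and the rest have no value in that set. The sets share no library, but how the authors chose the genes of either table is not given in the sources used here.

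Hearts stored with BM MSC CM were compared with 6h-I to ask what that preparation changed during storage. Cldn5 (chromosome 16, 18776847 to 18778262) was the single gene past the threshold: it was lower with BM MSC CM, at 30.2 ± 4.26 CPM (n = 3) against 59.4 ± 9.97 CPM (n = 3) in 6h-I and 25.3 ± 0.80 CPM (n = 2) in baseline C. Its log2 fold change was -0.95 (SE 0.19, 95% interval -1.37 to -0.53, limma adjusted p = 0.0296), and all 3 libraries lay below every 6h-I library. The genes appear to have been picked on these same 6h-I libraries, in which Cldn5 was high. Such picking favours a lower value in any group compared with them, so the p-value and the separation may overstate the difference. Cebpb, a transcription factor of the acute-phase response named here after its values were seen, had a log2 fold change of -0.77 (adjusted p = 0.0786). Hspa1a was at 3.53 ± 1.16 CPM against 8.96 ± 5.49 CPM (log2 -0.96, adjusted p = 0.269), Nppb at 193.3 ± 76.6 against 273.8 ± 76.2 CPM (-0.53, adjusted p = 0.298), Atf3 had a log2 difference of -0.58 (adjusted p = 0.313), and Dbp was at 40.1 ± 23.3 against 14.3 ± 7.98 CPM (1.37, adjusted p = 0.298), none of them past the threshold.

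No member of the circadian, immediate-early, hypertrophy or matrix lists passed in this comparison, over the table or adjusted over the list alone. The point estimates of the hypertrophy list were lower in 5 of 5 and those of the matrix list in 4 of 4, and 8 of 11 clock genes had higher estimates. Ctgf and Thbs1 are in both the hypertrophy and the matrix list. Among all genes tested, 82 of 85 estimates moved against the storage change, so these counts do not single out the lists. At an unadjusted p under 0.05, 13 of 85 genes differed. The Cldn5 call ended without baseline C 1' or 2', without 6h-I 1' or 4', and without BM MSC CM 2 or 3 (0 genes each); without 6h-I 3', 4 genes passed. It also ended with added terms, as the fold shrank and its error grew: the log2 fold change was -0.83 (SE 0.22, adjusted p = 0.128) with the replicate number as a block and -0.76 (SE 0.22, adjusted p = 0.067) with neighbouring barcodes as a block. Over the non-clock genes of the stored hearts it went from -0.95 (SE 0.20, adjusted p = 0.0214) to -0.89 (SE 0.21, adjusted p = 0.0983) with each library's clock position as a term. The median 95% interval reached 0.44 to either side on the log2 scale.

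Ad MSC CM was compared with 6h-I in the same way. Cldn5 was at 42.6 ± 8.19 CPM (n = 4), a log2 difference of -0.48 from 6h-I (SE 0.18, adjusted p = 0.377), and Adamts4 had a difference of -0.51 (adjusted p = 0.377). Hspa1a was at 4.48 ± 1.23 CPM (log2 -0.67, adjusted p = 0.497), Atf3 at 8.49 ± 2.92 CPM (-0.42, adjusted p = 0.5) and Dbp at 37.4 ± 32.2 CPM (1.03, adjusted p = 0.497). Nppb was at 335.2 ± 20.4 CPM, 0.33 above 6h-I on the log2 scale (adjusted p = 0.5). With limma 0 of 85 genes passed, the smallest adjusted p was 0.229 (Gm11992), and 7 genes had an unadjusted p under 0.05. No list member passed over the table or adjusted over the list alone, and 9 of 11 clock genes had higher estimates than in 6h-I. Among all genes tested, 74 of 85 estimates moved against the storage change, so this count does not single out the clock list. Without 6h-I 3', 1 gene passed.

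The preparations were also compared with each other. Nppb had the lowest p: it was lower with BM MSC CM than with Ad MSC CM by 0.86 on the log2 scale (SE 0.25), 193.3 ± 76.6 against 335.2 ± 20.4 CPM, with an adjusted p of 0.405. Cldn5 differed by -0.47 and Hspa1a by -0.28, with adjusted p-values of 0.405 and 0.911. Dbp and Atf3 differed by 0.34 and -0.16, both with an adjusted p of 0.911. With limma 0 of 85 genes passed, 9 had an unadjusted p under 0.05, and in the hypertrophy list 1 gene passed when adjusted over the list alone. Without BM MSC CM 2, 2 genes passed. The median 95% interval, unadjusted, reached 0.41 to either side, so that for a typical gene a smaller difference could not be told from 0. Larger differences could miss the threshold too, as that of Nppb did.

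**Figure D2:**
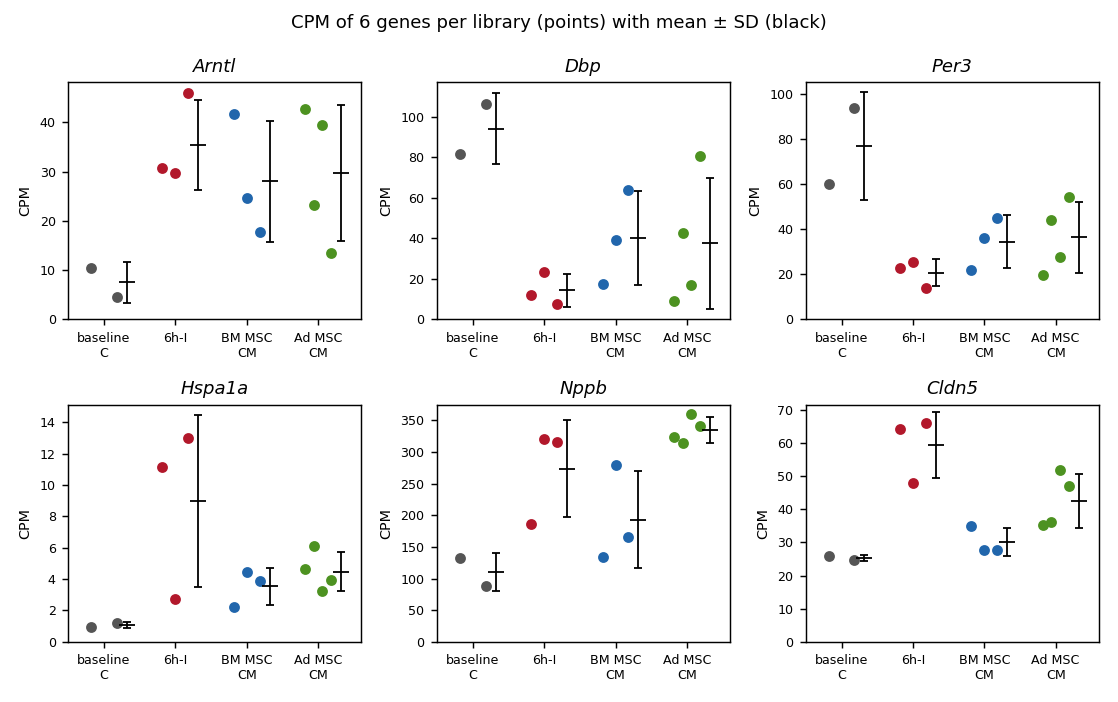
CPM of Arntl, Dbp, Per3, Hspa1a, Nppb and Cldn5 in each library of the media table (points, by group on the horizontal axis; n = 2, 3, 3 and 4), with the group mean and SD in black. All 3 BM MSC CM libraries lie below the 6h-I libraries for Cldn5, while Dbp ranges from 9.27 to 80.8 CPM among the 4 Ad MSC CM libraries.

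To ask whether the preparations countered the storage change, the direction of each gene's difference from 6h-I was set against its change with storage. With BM MSC CM, 82 of 85 genes (96.5%) moved against the storage change, and with Ad MSC CM 74 of 85 (87.1%). Because both comparisons use the same 6h-I libraries, the shares were set beside simulated unchanged groups. Simulations without any storage effect gave 64.7% and 66.0% on average and reached the observed shares in 0.1% and 5.9% of draws, and simulations that kept the storage effect gave 50% and 49.9% and reached them in 0.1% for both. Genes are not independent, and with 3 6h-I libraries the controls could not be divided, so part of the excess may come from them. Neither simulation modelled the apparent picking of genes on these 6h-I libraries, which alone can give opposite signs and lower positions. The simulated percentages are therefore not the chance of such shares or positions without an effect. The mean position on the storage change, from 0 in baseline C to 1 in 6h-I, was 0.68 ± 0.18 (n = 3) with BM MSC CM and 0.77 ± 0.19 (n = 4) with Ad MSC CM. All BM MSC CM positions (0.48 to 0.81) lay below those of 6h-I (0.85 to 1.08), while those of Ad MSC CM (0.56 to 0.99) overlapped them. On the storage change of the other set of hearts, over the 27 genes in both tables, BM MSC CM (0.53 to 0.86) overlapped 6h-I (0.86 to 1.26) as well, by 1 library (exact permutation p = 0.2, adjusted p = 0.3; for Ad MSC CM p = 0.171, adjusted p = 0.3), and on the clock genes it overlapped too (0.38 to 0.99 against 0.86 to 1.21, p = 0.3). The exact permutation test gave p = 0.1 for BM MSC CM against 6h-I, the smallest p that 3 against 3 allows, so that it could not pass, and p = 0.114 for Ad MSC CM (adjusted p = 0.171 for both). In the simulations that kept the storage effect a mean position as low arose in 0.5% of draws for BM MSC CM and in 3% for Ad MSC CM. Here too the picking of genes was not modelled. The preparations differed by -0.09 (exact permutation p = 0.571, adjusted p = 0.571).

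**Figure D3:**
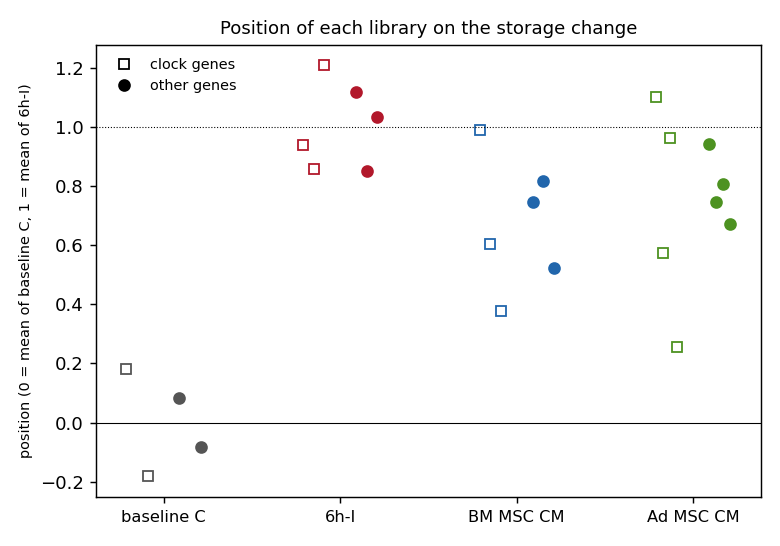
Position of each library of the media table on the storage change (vertical axis, no unit; 0 is the mean of baseline C and 1 the mean of 6h-I), for the clock list (open squares) and for all other genes (filled circles), by group. Clock positions of the Ad MSC CM libraries spread from 0.26 to 1.10, wider than their positions on other genes, which lie between 0.67 and 0.94.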

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

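The tests of the explanations for the clock genes and the splits of samples were chosen after their results had been seen.

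The storage change differed between the 2 sets of hearts for 2 of the 27 genes in both tables, by the limma term for the difference (adjusted p = 0.00942 for both). Dbp fell by 0.68 on the log2 scale in the storage table and by 2.75 in the media table, a difference of -2.07 (SE 0.45), and was lower in every 6h-I heart than in every baseline C heart of its set. This fit held only baseline C and 6h-I libraries. In the media-table fit, whose spread also takes in the preparations, the Dbp change alone had an SE of 0.75. The call for Dbp may therefore depend on which libraries set the spread. Gm11992 (chromosome 11, 9048594 to 9069356), a low gene in both tables, was higher in all 6h-I libraries of the storage table (0.57) and lower in all of the media table (-0.90), a difference of -1.47 (SE 0.31).

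In 9 of 79 gene and group combinations of 4 libraries, 1 library stood far from the rest, where chance gives about 1 in 20, or 4.0. Of 6 such values in the storage table, 5 belong to baseline C a, each on the side of the stored hearts: Nppb at 183 CPM (others: 74.9 to 79.7), Spon2 at 6.08 CPM (1.22 to 1.44), Hlf at 43.9 CPM (53.5 to 54.0), Timp3 at 268 CPM (363 to 372) and Herpud1 at 271 CPM (383 to 402). The sixth is Acot1 at 12 CPM in baseline C c (8.99 to 9.39). Without baseline C a, 234 genes passed in the storage comparison, against 246 with it. In the media table the values are Dixdc1 at 11.4 CPM in Ad MSC CM 2 (7.55 to 8.19), Eln at 59.0 CPM in Ad MSC CM 3 (50.7 to 51.5) and Hlf at 39.6 CPM in Ad MSC CM 4 (21.7 to 24.7).

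Most clock genes present were lower after storage in both sets, 9 of 10 in the storage table and 8 of 11 in the media table. The list passed Fisher's exact test in the storage table only (adjusted p = 0.0475, against 0.0937 in the media table), and there not with every library left out. Decay of short-lived transcripts in the cold argues for falls alone, and 3 clock genes, Arntl, Npas2 and Nfil3, rose 2.37-fold or more in the media table. These rises argue against decay as the whole cause. They do not exclude it, because CPM is relative and a loss of other transcripts raises the share of stable ones. The amount of RNA per heart was not examined here. Another time of day at collection stays open: hearts of 1 group, all stored for 6 h, differed in clock position by up to 0.85 of the storage change, but no label gives the time at which a heart was taken. Time of collection and storage therefore cannot be told apart for these genes, and a clock that runs on in the stored heart was not tested.

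Other splits of the libraries were counted for each comparison. For 6h-I against baseline C 1 of 35 splits, the real one, gave 246 genes, and the highest other gave 41; since the genes were picked on the real split, this does not exclude chance. For BM MSC CM against 6h-I, 2 of 10 splits gave as many genes as the real one, which gave 1, as did the highest other; 10 splits are too few for a share under 0.05. For Ad MSC CM against 6h-I and for BM MSC CM against Ad MSC CM the real split gave 0 genes (limma; 7 and 9 at an unadjusted p under 0.05), so that all 35 of 35 splits gave as many by construction and the count decides nothing. The highest other splits gave 5 and 9 genes, and whether this exceeds what chance gives was not tested.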

How the results depend on the processing

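The storage calls depended on the threshold: 153 genes passed at an adjusted p of 0.01, 33 and 1 with an absolute log2 fold change over 1 and over 2, and 122 of the 128 with the higher mean (fewer genes tested). Leaving out 1 library gave 183 (without 6h-I c) to 248. For the same comparison in the media table, 32 and 5 genes passed at those fold thresholds, 43 among the genes with the higher mean, and 56 (without baseline C 2') to 85 with 1 library left out. For BM MSC CM against 6h-I the count was 0 at an adjusted p of 0.01, at either fold threshold and, chosen after seeing the data, with clock position as a term and with neighbouring barcodes as a block; leaving out 1 library gave 0 to 4. For Ad MSC CM against 6h-I and BM MSC CM against Ad MSC CM, 1 gene each passed with neighbouring barcodes as a block, and leaving out 1 library gave 0 to 1 and 0 to 2. The cause was not tested where fewer samples or a stricter threshold do not give it.

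With the replicate number as a block, 0 genes passed for each preparation against 6h-I and for BM MSC CM against Ad MSC CM, and 85 for 6h-I against baseline C in the media table; same-numbered BM MSC CM and Ad MSC CM libraries correlated at 0.74, 0.05 and -0.39, so not every pair deviated together and the numbers were not taken as pairs, although they follow the order of the barcodes. No paired analysis was possible in the storage table because its columns carry no replicate numbers. Shares against the storage change were 100% for both preparations over the 5 genes with a storage change over 2 on the log2 scale, too few to pass, and 85.9 to 97.6% (BM MSC CM) and 80 to 91.8% (Ad MSC CM) with 1 library left out. In the storage table the number of lists with a direction was 0 over an absolute log2 fold change of 1, 0 without the filter, and 0 to 2 with 1 library left out; in the media table it was 1 without genes of several lists, as the circadian list was then the single list tested and its p of 0.0234 needed no adjustment, and 0 with any 1 library left out. Other alternatives for these results (136) stayed within 1.5 times the count or on the same side of the threshold. Alternatives on recovered reads, both sets of hearts in 1 table, or a set test with a correlation were not run. Low genes such as Tnf, at 0.42 CPM in baseline C of the storage table, are limited by depth.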

Other observations

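The comparisons of each preparation with baseline C, the correlation of positions, the correlation over neighbouring barcodes and the comparison of transcript lengths between tables were chosen after seeing the data; the shift over genes in both tables and the correlation of length with the fold difference were set down before their results were seen.

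Hearts stored with a preparation still differed from unstored hearts on the listed genes. These genes appear to have been picked for a difference between vehicle-stored hearts and these same baseline C libraries. Such picking favours a difference from baseline C in any stored group, so the counts are not independent evidence of one. With Ad MSC CM 78 of 85 genes differed from baseline C (47 higher, 31 lower), and with BM MSC CM 52 (33 higher, 19 lower). Of the clock list 10 of 11 genes passed with Ad MSC CM and 5 with BM MSC CM; of the 5 hypertrophy genes 5 and 2 passed. Adjusted over the list alone, these were 10 and 2 for the clock list and 5 and 0 for the hypertrophy list. The counts rest on few libraries: for BM MSC CM the 52 became 5 without baseline C 2', 24 without baseline C 1', 22 without BM MSC CM 1 and 13 without BM MSC CM 2, and for Ad MSC CM the 78 became 14 without baseline C 2', 47 without baseline C 1' and 51 without Ad MSC CM 1. Whether the preparations differ in these counts was not tested as such, and the direct comparison gave 0 genes.

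Genes of several functions not in the lists above also changed with storage. In the storage table Gja5, a connexin of atrial and conduction tissue, went from 7.25 ± 1.17 to 12.8 ± 2.70 CPM and Relb, an NF-kB subunit, from 11.3 ± 0.83 to 16.7 ± 4.57 CPM, while Tnfsf10, the death ligand TRAIL, fell from 23.3 ± 4.42 to 14.1 ± 1.68 CPM and Top2a, of dividing cells, from 4.73 ± 1.39 to 2.62 ± 1.06 CPM. In the media table Kcna5, a potassium channel gene, was at 14.6 ± 3.38 CPM in baseline C, 31.8 ± 1.72 in 6h-I, 28.6 ± 10.2 with BM MSC CM and 29.7 ± 6.97 with Ad MSC CM. These genes belong to lists with fewer than 3 members past the threshold and were named after their values were seen.

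The mean positions of BM MSC CM and Ad MSC CM lay nearer to baseline C than that of 6h-I, without passing the position test. A candidate explanation is that the genes were picked where these 6h-I libraries were extreme, which predicts a smaller shift over the 27 genes in both tables. The shift of BM MSC CM there was 0.34, against 0.29 over the other 58 genes, which goes against the prediction. The spread of this difference was not estimated, as the simulated SD of 0.13 is that of the position over all genes. The explanation therefore stays open. Another is that libraries differ along the clock axis whatever their group: within groups, clock and other positions of the 10 stored hearts correlated at a Pearson r of 0.69 (permutation p = 0.051; 0.53 without the 2 libraries farthest out) and a Spearman rho of 0.75 (permutation p = 0.028), while with clock position as a term the median absolute log2 fold change for BM MSC CM went only from 0.25 to 0.211. Neighbouring barcodes handled together may add to it: over all 8 pairs of neighbouring barcodes between groups the mean correlation was 0.06 (range -0.66 to 0.74), as high in 0.365 of the 1728 exchanges of libraries within groups, which does not support it and leaves it open. Pairing each BM MSC CM library with a neighbouring Ad MSC CM barcode gave correlations of 0.74, 0.05 and 0.64, the highest sum of 24 pairings. That pairing was a choice among neighbours, as barcodes 24 and 25 adjoin too and correlated at -0.39. An effect of the preparations remains possible beside these, and these libraries cannot settle it.

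Long transcripts fell and short ones rose in the storage table. The ratio of median lengths, higher over lower genes, was 0.50 there (95% bootstrap interval 0.39 to 0.60), and 0.58 (0.44 to 0.68) over genes changed more than 1.5-fold. Loss of long transcripts in every stored heart stays open: in the media table, whose genes all changed more than 1.5-fold by the ratio of means, the ratio was 0.89 (0.65 to 1.35; permutation p = 0.78), and the intervals overlap. Preparation of the storage-table libraries stays open as well: over the 27 genes in both tables, length correlated with the fold difference between the tables at a Spearman rho of 0.21 across genes (permutation p = 0.30), genes not being independent. No biological explanation was tested for this pattern. The list tests of direction took no account of transcript length, and its bearing on them was not tested.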
